A study of Homo sapiens with 6 samples.

How the data were processed

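RNA of 6 samples of MDA-MB-231 cells was sequenced, 3 with a control shRNA (shCTL) and 3 with an shRNA against HSF1 (shHSF1). Per the labels' protocols, RNA was extracted with a Qiagen column kit and libraries were made with a KAPA mRNA kit. The authors deposited a table of RPKM values (reads per kilobase of gene length and per 1000000 reads assigned to genes) for 28058 genes. Per the submitters' processing notes the tools STAR and featureCounts and the build hg38 were used; their versions, the annotation release and whether counting used strand are not given in the sources used here, so antisense and overlapping genes could share reads. Samples were grouped by their titles. The control columns of the table are named shScr, where the titles say shCTL, and were taken as shCTL because shHSF1 is the other shRNA in the table, with replicates matched by number. All 6 column names also hold the letters TGL, and cl before the replicate number, whose meanings are not given in the sources used here.

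In each column the deposited RPKM values times gene length in kb summed to 1000000, and 100% of them were whole multiples of 1 read within a tolerance of 0.01. Reads were recovered in this way. The totals assigned to genes were 70449758 for shCTL 1, 39090930 for shCTL 2, 36737836 for shCTL 3, 42615678 for shHSF1 1, 38705161 for shHSF1 2 and 33988307 for shHSF1 3. For a gene of 1 kb, 3 reads correspond to 0.0426 RPKM in the deepest library and 0.0883 RPKM in the shallowest. Intervals and floors given here cover counting error only. Within groups, chi-square per gene between pairs of libraries lay between 16.7 and 52.5, above sampling noise for each pair, so no library was counted as a repeat of another.

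Genes with at least 0.5 RPKM in at least 3 libraries (12433) were tested with limma 3.58.1 in R 4.3.3 (linear model on group, empirical Bayes with a mean-variance trend) on log2(RPKM + 0.5), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This was the branch planned for normalized values; the branch planned for a table of counts did not apply, and its alternatives were not run. HSF1 was also tested with an exact permutation test. Gene lists fixed before the data were examined (21 with at least 3 tested members) were compared with all other tested genes by camera of limma, with a preset correlation of 0.01 and adjustment over the 21 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. A list of mitochondrially encoded genes was not analysed here. The 27 entries whose gene names had turned into dates, 18 of them tested, were kept in the counts and not named. Gene types and GC content came from GENCODE v29, in which 97.2% of the tested symbols were found. Coordinates are those of the table, on hg38. The table's gene lengths include exons listed again on alternate contigs, which lowers the RPKM of such genes in all libraries alike.

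Named genes followed a rule fixed at the same time as the lists. It takes HSF1 and CCL5, then the 10 largest rises and the 10 largest falls among genes past the threshold whose group values do not overlap and whose higher mean is at least 1 RPKM, and from each list up to 4 members per direction with the largest change, or, where no member passes, 2 members with the highest level. Clone and locus names are left out. A few genes that the rule takes are not reported here. Genes named outside it are said to have been chosen after their values were seen.

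Whether replicate numbers pair the samples was checked on the deviations from group means. Samples with the same number correlated at 0.468, 0.307 and 0.451, and those with different numbers between -0.37 and -0.02, so the numbers were taken to pair the samples. The decision rests on these values; no label states what a number marks, though the column names end in running numbers that are consecutive within each same-numbered pair, whose meaning is not given in the sources used here. Tests reported here keep the planned model on group alone, which leaves this pairing out of account, except where the block is named. A fit with the replicate number as a block called 3257 genes higher and 2750 lower.

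Alternatives fixed beforehand were the block, leaving out each library, other filters on low values, pseudocounts of 0.1 and 1, median scaling, quantile normalization, a robust prior, no mean-variance trend, a fold limit and the other set tests. Chosen after seeing the data were limma with voom on the recovered reads, libraries thinned to the smallest total, leaving out genes on shifted chromosome segments, centring on windows of neighbouring genes, and leaving out genes listed again on alternate contigs. Windows held about 40 tested genes, and their limit came from 1000 shuffles of gene positions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

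The steps were tested on 5 sets of simulated data, drawn for the genes of the table and filtered anew in each set by the rule used for the real data. Of simulated genes changed by 0.5 on the log2 scale 47.3% were called, of those changed by 1 99.4%, and of those changed by 2 100%. No list without a shift was called by camera (0 of 105), and a lowered list was called in 5 of 5 sets. The simulated genes were drawn independently of each other, with a dispersion of 0.01, so members of a list shared no variation. In the real data the correlation estimated for the 9 lists that camera called lay between 0.16 and 0.58. The simulation therefore cannot tell how often camera with its preset correlation calls correlated lists wrongly. Of 914 genes called, 90 (9.85%) were unchanged ones, above the nominal share of 0.05. Over the 5 sets 330, 335 and 335 genes were changed by 0.5, 1 and 2, against 60451 unchanged ones, whereas 33.8% of the genes were called in the real data. The shares of changed genes found and of false calls depend on how many genes change. They therefore do not carry over to the real comparison.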

Results

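RNA from MDA-MB-231 cells, an established human cell line derived from a triple-negative breast adenocarcinoma, was sequenced in 6 libraries. In 3 of them the cells expressed a control short hairpin RNA (shCTL), and in the other 3 an shRNA directed against HSF1 (shHSF1), the transcription factor that drives the heat shock response. The comparison asked how gene expression differed when HSF1 was lowered, with attention to the chemokine CCL5, which the series title names. Levels were RPKM values for 28058 genes on hg38, and the gene-assigned reads behind them ranged from 33988307 in shHSF1 3 to 70449758 in shCTL 1. On the first principal component, which held 71.1% of the variance, the shCTL libraries lay between -30.8 and -26.9 and the shHSF1 libraries between 27.4 and 30.4. The labels do not say whether the replicates were separate cultures, and the columns of the table carry the letters cl before the replicate number, whose meaning is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical.

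HSF1 itself (chromosome 8, 144291569 to 144314726, plus strand, 13 exons) was lower in every shHSF1 library. Its level was 54.1 ± 6.70 RPKM (SD, n = 3) in shCTL and 4.52 ± 0.604 RPKM (SD, n = 3) in shHSF1. The shCTL libraries held 61.2, 53.3 and 47.9 RPKM and the shHSF1 libraries 5.01, 4.70 and 3.84 RPKM, from 17736 and 1144 reads per group. The log2 fold change was -3.44 (SE 0.123, limma adjusted p = 3.78e-06), where log2 fold changes are on the log2(RPKM + 0.5) scale, which understates those of low genes. Changes written as a number of folds are instead ratios of group mean RPKM without the added 0.5, except where reads are compared. For low genes they are larger than the tested changes. The exact two-sided permutation p was 0.1, the smallest that 10 splits of the libraries can give. This test treats the libraries as exchangeable and leaves the pairing by number out of account, and a paired version was not run. HSF2, a related heat shock factor chosen after its values were seen, was at 9.75 ± 0.458 RPKM in shCTL and 11.1 ± 0.642 RPKM in shHSF1 and did not pass the test (log2 fold change 0.18, limma adjusted p = 0.132).

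**Figure D1:**
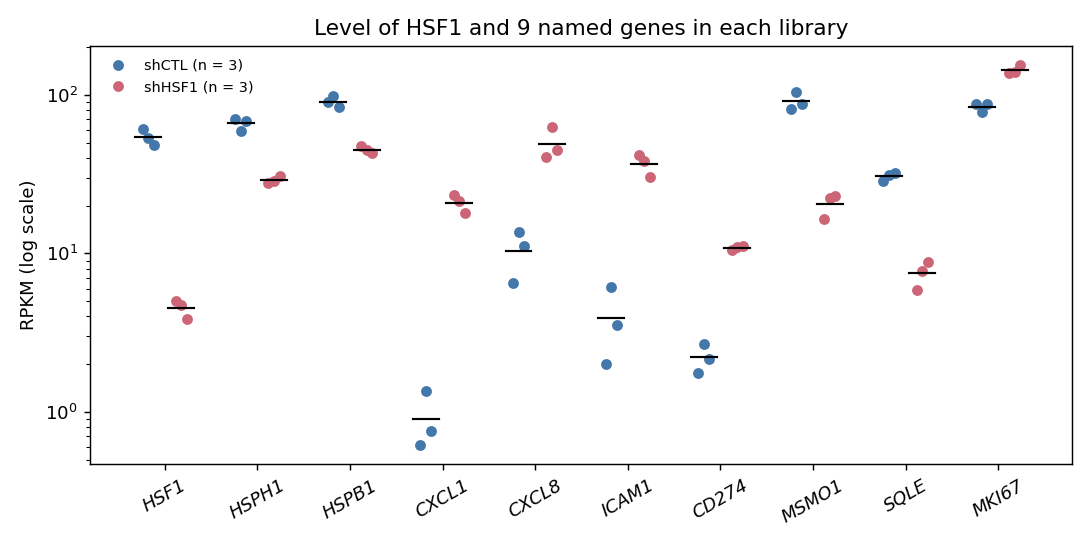
Level of HSF1 and 9 other named genes in each library, in RPKM on a log axis; points are single libraries (3 per group) and black lines are group means. HSF1 fell from a mean of 54.1 to 4.52 RPKM, CXCL1 rose from 0.908 to 20.9 RPKM, and for each gene drawn the points of the groups do not overlap.

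Of 12433 genes tested with limma, 2195 were higher and 2006 were lower in shHSF1 at an adjusted p under 0.05, which together made 33.8% of the tested genes. With a log2 fold change of at least 1 as well, 238 genes were higher and 370 lower. The group values did not overlap for 5897 genes (47.4%), where chance gives 10% if the 6 libraries are exchangeable, which leaves the pairing by number out of account. The count of higher genes was 1404 without shCTL 3 and 1383 without shHSF1 2.

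The largest rise among the genes the naming rule admits was that of SAA1 (chromosome 11, 18266225 to 18269976), an acute-phase serum amyloid protein, from 0.256 ± 0.108 to 57.8 ± 19.9 RPKM (SD, n = 3, log2 fold change 6.22, limma adjusted p = 4.23e-06). SAA1 shares sequence with its neighbour SAA2, so the division of reads between the genes is uncertain. LCP1, an actin-bundling protein of blood cells, rose 26.0-fold to 34.1 ± 2.74 RPKM (SD, n = 3). CXCL1 (chromosome 4, 73869392 to 73871302), a neutrophil-attracting chemokine, rose from 0.908 to 20.9 ± 2.74 RPKM, and ICAM1, an adhesion molecule for leukocytes, rose 9.48-fold to 36.8 ± 5.83 RPKM. CD40, a receptor of the TNF family, rose from 0.172 to 9.11 RPKM, and TGM2, a protein-crosslinking enzyme, from 6.59 to 88.6 RPKM. BCHE, which encodes butyrylcholinesterase, had no reads in shCTL and 1132 in shHSF1, which makes it at least 479-fold higher against a floor of 3 reads over the shCTL group. EMC10, a subunit of a membrane protein insertase, rose from 0.0573 to 4.90 RPKM, and FRG1CP, a pseudogene whose reads can be shared with its relatives, from 0.429 to 9.31 RPKM.

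The largest fall was that of EPB41L3 (chromosome 18, 5392276 to 5628991), a membrane skeleton protein, from 30.5 ± 1.75 RPKM (SD, n = 3) to 3 reads in the whole shHSF1 group, all of them in shHSF1 3 (log2 fold change -5.94, limma adjusted p = 5.86e-08). Its ratio of 6307 after scaling to depth had a 95% counting interval of 2158 to 30583. GLUL, the glutamine synthetase, fell from 29.4 ± 0.825 to 0.133 ± 0.0208 RPKM (SD, n = 3). HS6ST2, a heparan sulfate sulfotransferase, fell from 7628 reads to 1, a ratio of 6013 (interval 1079 to 237533), and MEST, an imprinted gene, from 3772 reads to 2, a ratio of 1487 (interval 411 to 12281). OLFML1 fell 37.2-fold from 10.1 RPKM, and MYO1D, an unconventional myosin, fell 16.3-fold from 18.9 RPKM. GSPT2, a translation termination factor, fell from 7.75 to 0.0292 RPKM (0.0149 without shHSF1 1). PPP2R2C, GYPC and CYFIP2 fell from 8.34, 12.6 and 6.46 RPKM to 0.0357, 0.446 and 0.0433 RPKM, and these 3 genes lie on chromosome segments with shifted levels, described next.

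Neighbouring genes moved together along parts of several chromosomes, in a scan chosen after the data were seen. In 313 windows of about 40 neighbouring tested genes, 38 had a median log2 fold change, relative to that of all genes, beyond 0.269, the 95th percentile of the largest window value in 1000 shuffles of gene positions. They formed 10 segments. Genes from 101 to 242 Mb of chromosome 2 had a median log2 fold change of -0.45 (451 genes), and genes of chromosome 4 had -0.35 from 0.0533 to 53.4 Mb (160 genes) and -0.42 from 75.5 to 188 Mb (268 genes). The median was 0.61 from 59.1 to 102 Mb of chromosome 15 (234 genes) and 0.56 from 78.6 to 114 Mb of chromosome 13 (73 genes). Smaller shifts, from -0.30 to -0.29, lay on the distal part of chromosome 5 (127 genes), on 2 parts of chromosome 8 (40 and 29 genes, the second of which holds the HSF1 locus) and on 2 parts of chromosome 11 (80 and 59 genes). On the segments 956 of 1521 genes (62.9%) passed the limma threshold, against 3245 of 10912 (29.7%) elsewhere. A higher share there follows in part from the choice of the segments, which were picked on these same fold changes. When the test was run without the segment genes, 1818 genes were higher and 1260 lower, in place of 2195 and 2006. With the shHSF1 values centred on each window, also chosen after seeing the data, 6 genes that the naming rule takes changed sign and 24 others lost their call, as given with their lists.

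**Figure D2:**
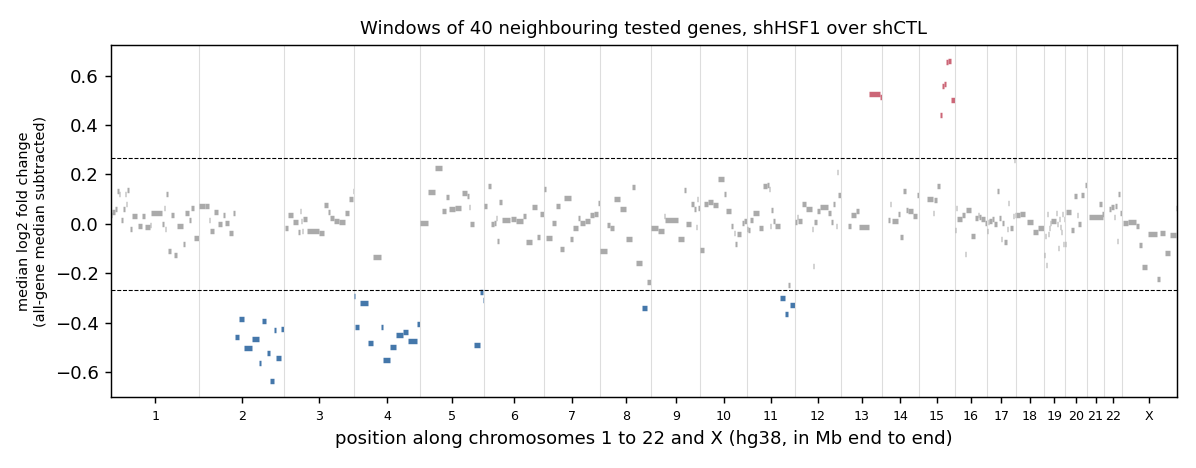
Median log2 fold change (shHSF1 over shCTL, with the median of all genes subtracted) of each window of about 40 neighbouring tested genes, against its position on hg38. Dashed lines mark the limit of 0.269 on either side of 0, blue and red bars are the 38 windows beyond it, and long runs of such windows lie on chromosomes 2, 4 and 15.

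CCL5 (chromosome 17, 35871491 to 35880373, minus strand) was listed at 0 in all 6 libraries, so its level could not be compared between the groups. A count of 0 allows up to 0.0162 RPKM in shCTL 1, 0.0293 in shCTL 2, 0.0311 in shCTL 3, 0.0268 in shHSF1 1, 0.0295 in shHSF1 2 and 0.0337 in shHSF1 3, as counting error only and only for reads that the table kept. The annotation of the table lists 99.9% of the exon length of CCL5 again on an alternate contig. The gene length behind these limits counts both places, so for the exons on chromosome 17 alone the limits would be higher. Of 673 protein-coding genes listed again in this way over nearly their full length, 636 (94.5%) had a mean under 0.5 RPKM, against 7323 of 18381 (39.8%) that had no alternate copy. The sets were not matched by kind of gene, and lengths that count the copies lower the RPKM of the first set. Genes used by every cell were among the 636, such as PFDN6, listed at 0, and the ribosomal protein gene RPS18, at a mean of 0.375 RPKM and 269 reads over the 6 libraries (both named after their values were seen).

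Among 23 listed chemokines, 6 were expressed well enough to be tested, and 4 of these rose in shHSF1 (also 4 adjusted over the list alone). Besides CXCL1, CCL2, a monocyte attractant, went from 1 read to 179, a ratio of 227 (95% counting interval 40.2 to 9018). CXCL8, the interleukin-8 gene, rose 4.73-fold from 10.4 ± 3.59 to 49.2 ± 11.8 RPKM (SD, n = 3). CCL28, a mucosal chemokine, was called at 1.81 and 2.59 RPKM, but its call was lost when any 1 of the 6 libraries was left out (limma adjusted p from 0.0630 to 0.119) or its window was centred (0.361). The chemokines rose as a list against all other genes (camera adjusted p = 0.00368), and this call was lost with an estimated correlation (adjusted p = 0.63). CCL3 and CCL4, named after their values were seen, were listed at 0 and, like CCL5, have an alternate copy.

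Targets of the inflammatory factor NF-kappaB and its cytokines rose most broadly. Of 22 tested members, 18 rose (18 adjusted over the list alone) and 4 did not pass the test, with a median log2 fold change of 1.03. IL1B, which encodes interleukin-1 beta, rose 6.79-fold to 15.3 ± 2.30 RPKM (SD, n = 3), IL1A 10.2-fold to 3.96 ± 0.665 RPKM, and IL32, another cytokine, from 0.121 to 3.20 ± 1.94 RPKM. Single libraries moved these values: without shCTL 2 the folds were 10.7 for IL1B and 16.3 for IL1A and the shCTL mean of IL32 was 0.0786 RPKM, and without shHSF1 1 the shHSF1 mean of IL32 was 2.08 RPKM. IL1A and IL1B rose although both lie on the segment of chromosome 2 whose median fell. The list was called by camera (adjusted p = 7.39e-07), not with an estimated correlation (adjusted p = 0.63), and it was called again with genes of the shifted segments left out (adjusted p = 2.31e-06).

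Among interferon-stimulated genes more fell than rose. Of 31 tested, 13 fell, 3 rose and 15 did not pass the test (13 and 3 adjusted over the list alone), with a camera adjusted p of 0.0134 for the list and an adjusted p of 0.756 with an estimated correlation. OAS1, a sensor enzyme for double-stranded RNA, fell 16.0-fold from 4.95 ± 1.07 to 0.309 ± 0.0855 RPKM (SD, n = 3). IFI6 fell 2.27-fold, IFIT1 2.33-fold and OASL 2.82-fold. The members that rose were IRF1, a transcription factor, by 1.65-fold, GBP1, a guanylate-binding protein, by 1.55-fold, and DDX58, the RNA sensor RIG-I, by 1.53-fold.

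For antigen presentation by MHC class I the table was a poor guide, because 11 of the 18 listed genes have an alternate copy. Of 11 tested members, 4 rose and 1 fell (4 and 1 adjusted over the list alone), and the list was not called against other genes (camera adjusted p = 0.437), while fry, which asks whether members move on balance one way, called it upward (adjusted p = 0.0353). ERAP1, a peptide-trimming aminopeptidase, rose 2.08-fold to 22.7 ± 1.12 RPKM (SD, n = 3). The calls of its relative ERAP2 (1.40-fold), TAPBP (1.64-fold) and B2M (from 45.3 to 54.3 RPKM), the latter 2 with an alternate copy, were weak. That of TAPBP was lost without any 1 of the 6 libraries (limma adjusted p from 0.0601 to 0.147) and with the replicate number as a block (adjusted p = 0.0503). That of ERAP2 was lost with every library but shCTL 2 left out in turn (up to 0.0883), and that of B2M without shCTL 1, shCTL 3, shHSF1 1 or shHSF1 2 (up to 0.0804). CANX, the calnexin gene on the shifted part of chromosome 5, fell 1.42-fold. Centring on windows ended the calls of CANX (limma adjusted p = 0.128), B2M (0.107), ERAP2 (0.0558) and TAPBP (0.0543).

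Immune checkpoint ligands and other suppressive molecules were not called as a list against other genes (camera adjusted p = 0.437) but were called upward by fry (adjusted p = 0.0140), with 4 of 11 higher and 2 lower (5 and 2 adjusted over the list alone). CD274 (chromosome 9, 5450503 to 5470567), which encodes PD-L1, rose 4.93-fold from 2.20 ± 0.457 to 10.9 ± 0.380 RPKM (SD, n = 3, log2 fold change 2.08, limma adjusted p = 4.23e-05). TGFB2 rose 2.01-fold, and CD276, which encodes B7-H3, rose 1.92-fold on the raised segment of chromosome 15. The other calls were small: NT5E was 1.19-fold higher, CD47 1.28-fold lower and TGFB1 1.18-fold lower. The NT5E call was lost without any 1 of the 6 libraries (limma adjusted p up to 0.103), the CD47 call without shCTL 2, shCTL 3, shHSF1 1 or shHSF1 2 (up to 0.0858), and the TGFB1 call without shCTL 2, shCTL 3 or shHSF1 2 (up to 0.119). Centring on windows also ended the calls of NT5E (0.0537) and TGFB1 (0.160).

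Among cytosolic heat shock proteins and their partners, the classical targets of HSF1, some fell and none rose. Of 24 tested members, 11 fell (12 adjusted over the list alone) and 13 did not pass the test, with a median log2 fold change of -0.30. HSPH1 (chromosome 13, 31134974 to 31162388), the HSP110 chaperone, fell 2.29-fold from 66.3 ± 6.03 RPKM (SD, n = 3), and HSPB1, the small heat shock protein HSP27, fell from 90.5 ± 7.20 to 45.2 ± 2.53 RPKM. HSPA4L, on the lowered part of chromosome 4, fell 1.76-fold, and FKBP4, a partner of HSP90, fell 1.58-fold. The inducible HSP70 genes HSPA1A and HSPA1B have alternate copies and were at 0.302 and 0.808 RPKM in shCTL (named after their values were seen). Over all 6 libraries their means were 0.256 and 0.803 RPKM. In the reads the table kept, the mean of HSPA1A was thus lower in shHSF1 than in shCTL, while that of HSPA1B hardly differed between the groups. HSPA1A, at no more than 0.320 RPKM in any library, was under the expression filter and was not tested. The list was called by camera (adjusted p = 2.32e-05) and not with an estimated correlation (adjusted p = 0.63).

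Among other protein-folding groups, 3 of 8 tested mitochondrial chaperones fell (3 adjusted over the list alone), namely HSPE1 by 1.75-fold, HSPD1 by 1.67-fold and CLPX, a protease subunit, by 1.32-fold. HSPE1 and HSPD1, which are neighbours, lie on the lowered part of chromosome 2, and CLPX on the raised part of chromosome 15. The camera call of this list (adjusted p = 0.0432; 0.721 with an estimated correlation) was lost without shCTL 1 (adjusted p = 0.127), shHSF1 2 (0.0584) or shHSF1 3 (0.0551), with the segment genes left out (0.702), with windows centred (0.270) and without the mean-variance trend (0.0561). Over the 20 alternatives that keep the preset correlation it ranged from 0.0192 to 0.702, and centring also ended the calls of HSPE1 (limma adjusted p = 0.244) and HSPD1 (0.0999). Chaperonin and prefoldin subunits were not called as a list (camera adjusted p = 0.174): of 13 tested, CCT6A fell 1.41-fold and PFDN5 1.27-fold, and PFDN2 was higher at 122 against 102 RPKM (adjusted over the list alone, 2 lower and none higher). This list was called, downward, without shCTL 2 (camera adjusted p = 0.0374) and with windows centred (0.0472), and ranged up to 0.422 over those 20 alternatives. The PFDN2 call was lost without any library but shHSF1 2 (limma adjusted p up to 0.120), and centring ended the calls of PFDN2 (0.260) and PFDN5 (0.0819). Chaperones of the endoplasmic reticulum and the unfolded protein response were not called either (camera adjusted p = 0.653). Of 16 tested, DNAJC3, on the raised part of chromosome 13, rose 1.58-fold, and HSPA5, the chaperone BiP, was 1.62-fold lower (1 higher and none lower adjusted over the list alone); the HSPA5 call was lost without any library but shCTL 1 (limma adjusted p up to 0.121), and that of DNAJC3 with windows centred (0.298). In the ATF4 pathway 1 of 16 tested genes passed the test (camera adjusted p = 0.883, direction downward against a median of 0.03 and a mean of 0.01), ATF4 itself, 1.29-fold lower, and it did not pass when adjusted over the list alone or without shCTL 2, shCTL 3, shHSF1 1 or shHSF1 3 (limma adjusted p up to 0.0939), nor with windows centred (0.0629). Of 30 proteasome subunits, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.166, with a call upward, at 0.0239, without shCTL 1 and values up to 0.497 over the same 20 alternatives): PSMA4, on the raised part of chromosome 15, rose 1.69-fold, PSMA3 1.35-fold and PSMC1 1.32-fold, PSMD7 was 1.17-fold higher, PSMB5 fell 1.71-fold, and PSMD1, on the lowered part of chromosome 2, was 1.25-fold lower. The PSMD7 call was lost with every library but shHSF1 3 left out in turn (limma adjusted p up to 0.0948), and the PSMD1 call without shCTL 3 (0.0618) or shHSF1 2 (0.0674). Centred on its window, PSMD1 was at a log2 fold change of 0.23, and the call of PSMA4 ended (0.411).

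**Figure D3:**
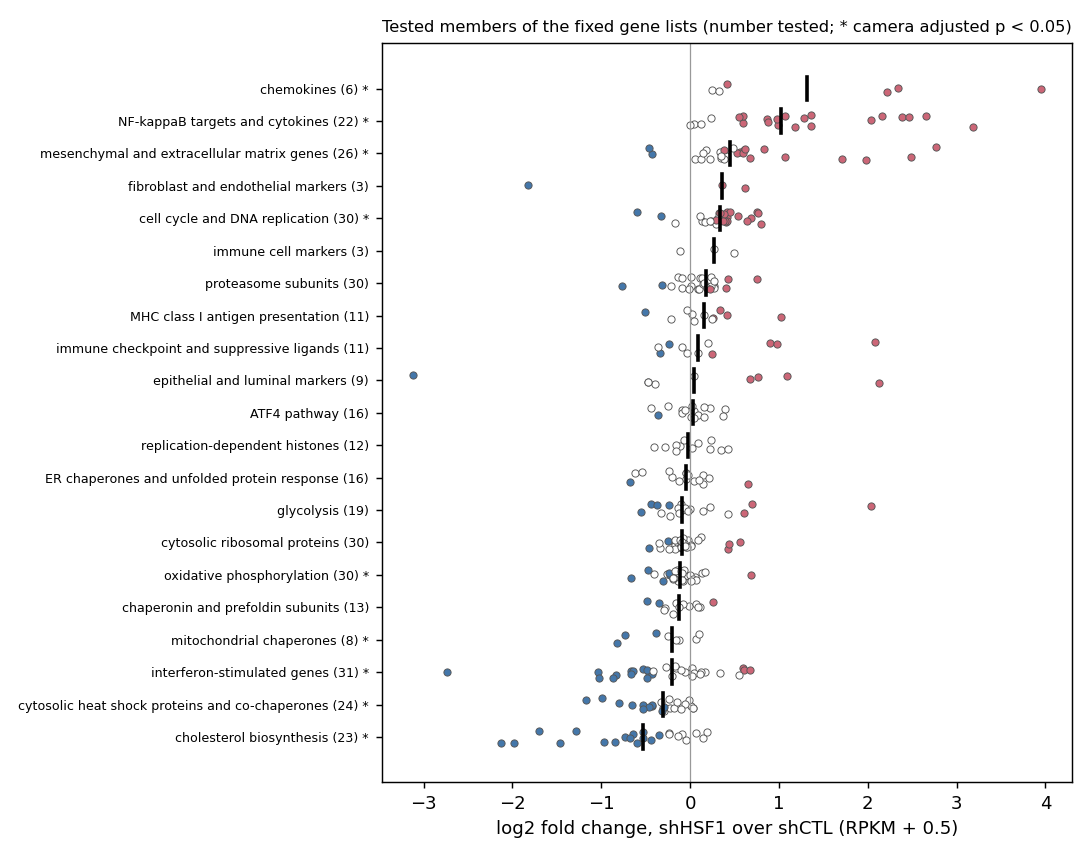
Log2 fold change (shHSF1 over shCTL, on RPKM + 0.5) of each tested member of the 21 gene lists with at least 3 tested members; filled points passed the limma threshold and black bars are list medians. NF-kappaB targets had a median of 1.03 and cholesterol biosynthesis genes a median of -0.53, and an asterisk marks the 9 lists called by camera with its preset correlation.

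Among genes of the cell cycle and DNA replication most rose. Of 30 tested, 19 were higher and 2 lower (22 and 2 adjusted over the list alone), with a median log2 fold change of 0.34, a camera adjusted p of 0.000155 and an adjusted p of 0.858 with an estimated correlation. AURKB, a mitotic kinase, rose 1.75-fold to 74.0 ± 8.66 RPKM (SD, n = 3), MKI67, the proliferation marker Ki-67, rose 1.71-fold to 144 ± 9.27 RPKM, and CCNE2, a cyclin of S-phase entry, rose 1.61-fold. CCNE1 was 1.74-fold higher, a call lost without shHSF1 1 (limma adjusted p = 0.0502). The lower members, the checkpoint kinase gene BUB1 (1.52-fold) and the helicase subunit gene MCM6 (1.26-fold), both lie on the lowered part of chromosome 2, and MCM6 was at a log2 fold change of 0.17 once centred on its window, where the call of BUB1 ended too (limma adjusted p = 0.198).

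Among cholesterol biosynthesis genes most fell. Of 23 tested members, 15 were lower (15 adjusted over the list alone) and 8 did not pass the test, with a median log2 fold change of -0.53 and a camera adjusted p of 1.97e-06 (adjusted p = 0.63 with an estimated correlation). MSMO1 (chromosome 4, 165327666 to 165343162), a sterol demethylase, fell 4.43-fold from 91.1 ± 12.2 to 20.6 ± 3.65 RPKM (SD, n = 3), and SQLE, the squalene epoxidase, fell 4.10-fold from 30.7 ± 1.77 to 7.48 ± 1.47 RPKM. Both lie on lowered segments, of chromosomes 4 and 8, but the list was called again without the segment genes (camera adjusted p = 2.31e-06). SC5D, a sterol desaturase, fell 2.87-fold.

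Among 30 tested nuclear-encoded genes of oxidative phosphorylation, 5 were lower and 1 higher (2 and 1 adjusted over the list alone), with a camera adjusted p of 0.0321 that was lost with an estimated correlation (adjusted p = 0.917), without shCTL 1 (0.191), without shHSF1 3 (0.236) and without the mean-variance trend (0.0519). Over the 20 alternatives that keep the preset correlation it ranged from 0.00507 to 0.236, and fry did not call the list (adjusted p = 0.256). NDUFB3 fell 1.60-fold and NDUFS1 1.39-fold on the lowered part of chromosome 2, and COX5A rose 1.61-fold on the raised part of chromosome 15. SDHD (1.23-fold lower, on a lowered part of chromosome 11) and NDUFA1 (1.18-fold lower) lost their calls without any library but shHSF1 2 (up to 0.0831) and shHSF1 1 (limma adjusted p up to 0.112), respectively. Centred on their windows, NDUFS1 was at a log2 fold change of 0.17 and SDHD at 0.063, and the calls of NDUFB3 (limma adjusted p = 0.137), COX5A (0.530) and NDUFA1 (0.0675) ended. Among 19 glycolysis genes, 3 rose and 4 were lower (4 and 4 adjusted over the list alone), without a call for the list (camera adjusted p = 0.653, direction downward, with a median of -0.09 and a mean of 0.08). ALDOC, an aldolase, rose 9.67-fold from 0.283 RPKM, SLC16A3, a lactate exporter, rose 1.64-fold, and PKM, the pyruvate kinase on the raised part of chromosome 15, rose 1.52-fold. HK2, a hexokinase, fell 1.48-fold and PFKM fell 1.37-fold. PGK1 (1.29-fold lower) lost its call without shCTL 1 (limma adjusted p = 0.0518) or shCTL 2 (0.0545), and PFKP (1.18-fold lower) without any 1 of the 6 libraries (up to 0.0838). Centring on windows ended the calls of PKM (0.793) and PFKP (0.188). Of 30 tested cytosolic ribosomal protein genes, 3 were higher and 2 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.278, with a call downward, at 0.0472, when windows were centred and values up to 0.969 over 20 alternatives). RPL37 rose 1.35-fold, RPL4, on the raised part of chromosome 15, 1.36-fold (-0.11 on the log2 scale once centred on its window), and RPL8, on the same lowered segment of chromosome 8 as HSF1, fell 1.38-fold, a call lost without the filter on low values (limma adjusted p = 0.0626) and with windows centred (0.437). RPLP1 was 1.49-fold higher, on chromosome 15, a call lost without shCTL 2, shCTL 3, shHSF1 1 or shHSF1 2 (limma adjusted p up to 0.0698) or with windows centred (0.985).

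Among mesenchymal and extracellular matrix genes more rose than fell. Of 26 tested, 13 were higher, 2 lower and 11 did not pass the test (15 and 2 adjusted over the list alone), with a median log2 fold change of 0.45, a camera adjusted p of 2.32e-05 and an adjusted p of 0.63 with an estimated correlation. TGFBI, an extracellular matrix protein, rose from 1.80 ± 0.420 to 15.1 ± 1.66 RPKM (SD, n = 3), and COL6A1 rose 3.52-fold. The basement membrane collagen genes COL4A1 and COL4A2, neighbours on the raised part of chromosome 13, rose 6.16-fold and 4.11-fold. ZEB2, on the lowered part of chromosome 2, was 1.43-fold lower and LOX, a collagen-crosslinking enzyme, 1.35-fold lower; both calls were lost without shCTL 2, shCTL 3, shHSF1 1 or shHSF1 2 (limma adjusted p up to 0.0872 and 0.0903). Centred on its window, ZEB2 was at a log2 fold change of 0.039.

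Of 20 epithelial and luminal markers 9 were tested, and 4 rose and 2 fell (4 and 3 adjusted over the list alone), without a call for the list against other genes (camera adjusted p = 0.653) but with a call upward by fry (adjusted p = 0.0170). The list had a median log2 fold change of 0.05 and a mean of 0.03, against a median of 0.04 over all tested genes. KRT7 rose 6.87-fold, GATA3, a luminal transcription factor, 2.44-fold, EPCAM 1.79-fold and ESRP2, a splicing factor, from 0.199 to 0.611 RPKM. CLDN4, a tight junction protein, fell 47.6-fold from 4.74 ± 1.07 RPKM (SD, n = 3; 82.3-fold without shHSF1 2), and KRT18 was 1.38-fold lower, a call lost without shCTL 1 (limma adjusted p = 0.0518) and with windows centred (0.102). Markers of other cell types were mostly under the expression filter. Of 16 immune cell markers 3 were tested, and limma called 0 (1 at an unadjusted p under 0.05, 0 with voom on the reads; camera adjusted p = 0.653). CD68 was at 77.5 ± 7.95 RPKM in shCTL and 94.0 ± 11.8 RPKM in shHSF1 and passed the test only without shHSF1 2 (limma adjusted p = 0.0465, against 0.107 with all libraries), and CD8A was at 1.10 and 0.974 RPKM. Of 16 fibroblast and endothelial markers 3 were tested (2 higher and 1 lower, also adjusted over the list alone; camera adjusted p = 0.883, fry adjusted p = 0.00685, downward). KDR, the VEGF receptor gene, fell 4.02-fold from 10.8 ± 0.441 RPKM (SD, n = 3), while COL1A1 was 1.70-fold higher and RGS5 at 0.959 against 0.638 RPKM, so that the list had a median of 0.36, a mean of -0.28 and a camera direction downward. The COL1A1 call was lost without shCTL 1, shCTL 3, shHSF1 1 or shHSF1 2 (up to 0.0698) and the RGS5 call without any 1 of the 6 libraries (limma adjusted p up to 0.101).

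Replication-dependent histone transcripts, which lack a poly(A) tail in most cases and serve as a sign of how RNA was selected, did not differ detectably. Of 12 tested, limma called 0 (0 at an unadjusted p under 0.05, 0 with voom; camera adjusted p = 0.883, direction downward, with a median of -0.02 and a mean of 0.01). HIST1H2BK was at 223 ± 98.3 and 160 ± 27.0 RPKM (SD, n = 3) in shCTL and shHSF1, and HIST1H1C at 87.0 ± 27.3 and 79.0 ± 17.7 RPKM. Mitochondrially encoded genes were not analysed here.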

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

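The alternatives chosen after seeing the data were voom on recovered reads, thinning, leaving out segment genes, window centring and leaving out genes with alternate copies. Of 105 named genes past the threshold, 67 kept direction and call in each alternative that tested them, and 38 did not. Of the 105, 71 were tested in all 20 alternatives fitted to genes and 53 of these kept both in all 20; the other 34 were left out of at least 1, as genes of low level, on segments or with alternate copies. Over the 6 fits without 1 library, 81 kept both. Without 1 library, higher genes numbered 1383 (without shHSF1 2) to 2374, with 1404 without shCTL 3, and lower genes 1399 to 1943. HSF1 lay between -3.53 and -3.34 on the log2 scale, and camera called 4 to 5 lists higher and 3 to 6 lower. HIST1H1C, not past the threshold, went from -0.34 without shCTL 2 to 0.11 without shCTL 1, and was at 0.00096 without shHSF1 3. These fits have fewer samples. The fold limit of 1 left 238 genes higher and 370 lower by its construction.

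Camera with an estimated correlation called 0 lists higher and 0 lower (0 at an unadjusted p under 0.05, lowest adjusted p 0.63), and fry called 7 higher and 5 lower. Both used the model on group alone. The correlation was thus estimated with variation shared by samples of the same number left in, and it was not estimated with the block. Without the mean-variance trend 3 lists were called lower in place of 5, as mitochondrial chaperones (camera adjusted p = 0.0561) and oxidative phosphorylation (0.0519) were lost; the cause was not tested. Without segment genes fewer genes were tested, and 1260 were lower and 1818 higher. Centring on windows, which subtracts the shift of each gene's neighbours, reversed PSMD1 (0.23), MCM6 (0.17), NDUFS1 (0.17), SDHD (0.063), RPL4 (-0.11) and ZEB2 (0.039), ended 24 other calls of named genes, and gave 1846 genes higher and 1500 lower. It shared 2944 calls with the 4201, 2932 of them in the same direction. Of the 9 lists called, 7 kept their call in all 20 alternatives that keep the preset correlation, none with the estimated one, and 8 with fry. Without the filter on low values 14 calls of named genes ended, among them PFDN2, HSPA5, ATF4, CCL28, ERAP2, NT5E, SDHD, RPLP1, RPL8, ZEB2, LOX, KRT18 and COL1A1. Median scaling ended 7 (among them PFDN2, PSMD7, CCL28, TAPBP, NT5E and RGS5), quantile normalization 6 (among them HSPA5, CCL28, TAPBP, PGK1 and RGS5), and leaving out the mean-variance trend 7 (among them PFDN2, HSPA5, NT5E, TGFB1, PFKP and NDUFA1). CCL28 also lost its call after thinning and without segment genes, and TAPBP with a pseudocount of 1.

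With the replicate number as a block, 3257 genes were higher and 2750 lower, 4200 of the 4201 calls were kept, and no list call changed; among named genes the call of TAPBP alone was lost. Voom called 2307 higher and 2060 lower (4081 shared), and thinning to the smallest library 2152 and 1981, so the greater depth of shCTL 1 moved the counts little. Median scaling, quantile normalization and voom turned the sign of no list median. CCL5 was listed at 0 in each library, so no alternative gave it a value, and depth limits what can be said of it to the floors of 3 reads. Alternatives planned for a count table were not run.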

Other observations

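Genes in the next 2 paragraphs, and the neighbours MAGED1 and L3MBTL4, were chosen after their values were seen. Tests chosen after the result was seen were those of random placement, of a second gene copy, of absent CCL5 transcription, of whole-segment shifts for nearly absent genes, and of the 4 such genes with a changed neighbour. The count of changed neighbours was planned, but the interval in its reading was added after the count was known.

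Several genes outside the fixed lists rose in shHSF1. PTX3, a soluble pattern recognition protein, rose from 29.7 ± 3.06 to 83.7 ± 10.4 RPKM (SD, n = 3, log2 fold change 1.48, limma adjusted p = 8.99e-05). SERPINB9, an inhibitor of the cytotoxic protease granzyme B, rose from 0.0948 to 4.44 RPKM, complement component C3 from 0.0503 to 2.33 ± 1.85 RPKM (1.29 without shHSF1 1), and INHBA, an activin subunit, from 0.223 to 3.01 RPKM. CD82, a tetraspanin, rose 8.06-fold to 73.9 ± 18.3 RPKM, COL7A1, the anchoring fibril collagen, 9.13-fold, L1CAM, an adhesion molecule, 3.44-fold, HBEGF, an EGF receptor ligand, 2.98-fold, and CTSD, a lysosomal protease, 2.75-fold to 337 ± 36.2 RPKM. Each of these calls was kept when any 1 library was left out.

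Among genes that fell were NUPR1, a stress-response regulator, from 8.71 ± 4.81 to 0.852 ± 0.473 RPKM (SD, n = 3, log2 fold change -2.66, limma adjusted p = 0.00343), and CLU, the extracellular chaperone clusterin, by 5.13-fold. The kinase gene SRC fell 9.43-fold, the endocytic receptor gene LRP1 5.37-fold, SORL1, a sorting receptor, 25.6-fold and LOXL4, a lysyl oxidase relative, 10.5-fold. The isocitrate dehydrogenase genes went opposite ways, each beyond the median shift of its chromosome segment. IDH1, the cytosolic enzyme, fell from 67.4 ± 8.18 to 18.3 ± 2.98 RPKM on chromosome 2 (log2 fold change -1.86, segment -0.45), and IDH2, the mitochondrial enzyme, rose from 2.50 ± 0.179 to 9.89 ± 0.703 RPKM on chromosome 15 (1.79, segment 0.61). On a lowered segment of chromosome 11 (median -0.30) IL18 and CASP1, which encodes the protease that matures interleukin-18, fell 3.67-fold and 4.62-fold.

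The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split alone (1 of 10) called as many as 4201 genes with limma, and the highest count of the others was 0 (up to 1164 at an unadjusted p under 0.05, against 5461 for the real split; voom was not run on them). The 3 others that, like the real split, part all 3 numbered pairs gave up to 47 genes at an unadjusted p, and the 6 that keep pairs together up to 1164.

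Runs of neighbouring genes moved one way on 10 segments. Random placement of changed genes is argued against by the 38 windows beyond the shuffled limit, and GC content or gene length by the 98.5% of the segments' shift kept (median over segments) after their trends were removed. A copy number difference between the cell populations is a candidate explanation: in 23 windows picked on every other gene, 88.0% of 458 remaining genes moved the way of their window, and genes of higher and lower level differed in shift by 0.07 on the log2 scale. The remaining genes lie in the same windows as the genes used for picking, so any shift of a whole region would give such agreement. These values therefore do not tell copy number from other causes of a regional shift. DNA was not analysed here, so a copy number difference stays a hypothesis. Populations derived separately cannot be parted from an effect of the HSF1 shRNA, which was not tested. Genes on these segments may thus owe part of their change to the segment.

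CCL5 was listed at 0 in each library. Loss of its reads to the copy on an alternate contig is a candidate explanation: of genes from lists every cell uses, 100% (5 of 5) with a full second copy lay under 0.5 RPKM, against 0 of 129 without one (Fisher's exact test, two-sided, p = 3.00e-09). Part of this contrast is built in, since the gene lengths count such copies and so lower RPKM without any loss of reads. In reads over the 6 libraries, which do not depend on length, these 5 genes held 1 (DNAJA3), 0 (PFDN6), 43 (PSMB3), 277 (RPS9) and 269 (RPS18). They were named after their values were seen. Some genes with such a copy, B2M among them, were well above that level. Absence of CCL5 transcription in both groups cannot be told apart from such a loss, since the limit of 0.0337 RPKM that 0 reads allow holds only for reads the table kept. That limit also uses a gene length that counts both copies, and would be higher on the exons of chromosome 17 alone. A biological explanation through HSF1 was not tested for this pattern.

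In 20 genes on 10 chromosomes a mean of at least 3 RPKM in 1 group stood against under 0.1 RPKM in the other, 13 of them nearly absent in shHSF1 and 7 in shCTL. The shifts of whole segments are argued against, since 17 of the 20 lay outside them. A deletion that spans neighbouring genes, as the cause for most of them, is argued against only weakly. A neighbour changed the same way by at least 2 on the log2 scale was found for 4 of 20 (20%, exact 95% interval 5.73% to 43.7%). The interval holds the stricter bound of 1 in 4 that was planned. It takes the genes as independent, though HS6ST2 and GPC4 are each the changed neighbour of the other. Some neighbours may also have been too low to reach such a change, so the interval does not exclude a majority. Among those 4 genes, a deletion that takes in both genes whole is argued against for GSPT2, whose neighbour MAGED1 held at least 4.92 RPKM in each shHSF1 library; it cannot be told apart from shared regulation for the other 3, of which 2, the adjacent HS6ST2 and GPC4, are nearly absent together, and EPB41L3 has L3MBTL4 at 0.144 RPKM beside it. Deletions whose neighbouring genes were too low to score may also remain. Loss of single genes, silencing in separately derived populations and an effect of HSF1 may each remain, untested.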
